A study of Mus musculus with 6 samples.

How the data were processed

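The series holds 6 RNA libraries from mouse hippocampal tissue, single-cell per the labels. Barcodes with no mitochondrial UMI made up 17.9% to 66.6% of a sample, and whether whole cells or nuclei were captured was not tested, so cell here means a barcode called as a cell. Per the labels, the mice were 6 months old and fell into 3 groups with 2 samples each: 5×FAD mice given PBS (5xFAD_PBS), 5×FAD mice given Aβ3FTnAu (5xFAD_Ab3FTnAu) and wild-type littermates given PBS (WT_PBS). The 5×FAD line carries human transgenes and builds up amyloid-β plaques, and Aβ3FTnAu is, from the series title, a protein and gold nanostructure aimed at such plaques. No source used here says whether the 2 samples of a group came from separate animals, so every p-value below measures spread between samples.

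The libraries were made with the 10x Genomics Chromium 3′ chemistry. The deposited matrices hold raw UMI counts per gene and cell barcode, written by the authors with Cell Ranger 7.1.0 per the file headers and against mm10 per the labels. They list 32285 genes and contain called cells alone, 50224 barcodes over the 6 samples. Whether introns were counted is not given in the sources used here. The submitters name Seurat 4.3.0.1 in their processing notes, and no table of their clusters or cell types was used here.

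All values were computed from the raw counts. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which left 44736 cells. Doublets were scored per sample with Scrublet in scanpy 1.11.5. Its automatic threshold called between 0.021% and 17.9% of a sample's cells, so the highest-scoring cells were removed instead, in the number expected from a rate of 0.8% per 1000 cells, 3080 in all. The 41656 cells left had median depths of 3957 to 5131 UMIs per sample. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components and 15 nearest neighbours went into Leiden clustering at resolution 1.0 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9), with no correction between samples.

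Clusters were named from 20 fixed marker lists. A cluster's score for a list was the mean log2 ratio of its CPM over the 10th percentile of all clusters, with 10 CPM added. The top list needed a score of at least 1.0 and 3 detected markers. A cluster whose second list, from another lineage, scored at least 1.5 and at least 0.6 of the first was left unnamed as a mixture, and so was a cluster with 5 or more mitochondrial transcripts among its 10 most specific genes. A cluster was also left out of its class when another lineage's list had more genes among those 10 than its own, or when it held none of its own markers there and its median depth was under 1/3 of the sample median. Cluster 27 scored highest for microglia (5.23). It met that last condition, with a median depth of 0.277 of the sample median and no gene of the fixed microglia list among its 10 most specific, but was kept as the one cluster led by that list. It is therefore called the microglia-marker cluster, not microglia. It carries the comparisons that were planned for microglia.

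Counts were summed per sample and class and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. All 6 samples entered 1 fit per class, with TMM factors, filterByExpr and Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change over the root of F. The comparisons were 5xFAD_PBS against WT_PBS, 5xFAD_Ab3FTnAu against 5xFAD_PBS and, for cluster 27, 5xFAD_Ab3FTnAu against WT_PBS. CPM values are means with SD over the 2 samples of a group. Class shares were tested with the same edgeR model on cell counts. Of 28 fixed gene lists, 25 had at least 4 tested members in some class and were tested with camera (limma 3.58.1, preset correlation of 0.01), again with an estimated correlation, and with fry. No list passed with the estimated correlation in any class or comparison. That adjusted p is given beside the called lists below.

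Named genes follow a fixed rule: up to 8 of the largest rises and 8 of the largest falls past the threshold with separated samples and a mean of at least 20 CPM, the 4 members with the smallest p of each called list, and genes set in advance per class. For a gene with no counts in a whole group, the fold is a lower bound against a floor of 3 counts over the group. For 1 to 3 counts, the ratio is given with an exact 95% counting interval. Intervals of cell shares are exact Clopper-Pearson 95% intervals, and for a share of 0 the limit is that of 3 counts of the total. Intervals and floors cover counting error only. Coordinates come from the GENCODE vM21 annotation (GRCm38), matched on gene ID.

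The test was tested on simulated data with 200 changed genes per class and comparison. In cluster 27, 42% of genes changed 2-fold and 92% of those changed 4-fold were recovered for 5xFAD_PBS against WT_PBS, with 10 false calls. For 5xFAD_Ab3FTnAu against 5xFAD_PBS, 35% and 75% were recovered, with 4 false calls. A raised list of 20 genes was called and 0 of 19 unchanged lists were. The simulated genes varied independently, with the same spread per gene in every group. Correlation between genes and the wider spread within WT_PBS were absent, so these rates may not hold for the real data.

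Groups, comparisons, tests, gene lists, marker lists, the rule for named genes and most alternatives were set before the data were examined. The alternatives were lenient and strict cell filters, doublets kept, Leiden resolutions of 0.5 and 2.0, RLE factors, DESeq2 1.42.0, no count filter, the replicate number as a block, fits of the 4 compared samples alone, equal cells per sample and each sample left out in turn. The replacement doublet rule, the score minimum and mixture thresholds of cluster naming, the treatment of clusters led by mitochondrial transcripts, the keeping of cluster 27, the minimum of 4 list members and of 10 cells per sample, the astrocyte-like class, and the alternatives with cells lacking a mitochondrial UMI, equal cells per cluster and shares over named classes were set after seeing the data. Reads, plaque measurements and images were not used here.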

Results

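Single-cell RNA counts were available for 6 hippocampal samples, 2 each from 5xFAD_PBS, 5xFAD_Ab3FTnAu and WT_PBS mice at 6 months of age. The samples held 8186 and 6594 barcodes in 5xFAD_Ab3FTnAu, 5196 and 9057 in 5xFAD_PBS, and 14993 and 6198 in WT_PBS. In the same order, total depths were 38647687, 39948850, 32528417, 42342460, 76780861 and 33689026 UMIs. Of the 41656 cells kept, 29112 (69.9%) were neuron-like, 3099 oligodendrocyte-like, 1162 oligodendrocyte precursor-like, 1036 astrocyte-like and 893 (2.14%) in cluster 27, the microglia-marker cluster. Clusters that were not named or were left out held 12.8% ± 0.592 of cells in 5xFAD_Ab3FTnAu, 14.9% ± 0.780 in 5xFAD_PBS and 16.7% ± 1.60 in WT_PBS (SD, n = 2 samples each). All means below are over 2 samples per group with SD, and errors of log2 fold changes are SE.

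Barcodes with no mitochondrial UMI made up 66.2% ± 0.560 in 5xFAD_Ab3FTnAu, 20.3% ± 3.40 in 5xFAD_PBS and 43.7% ± 19.3 in WT_PBS. This share therefore moved with the groups, and the 2 WT_PBS samples differed widely (57.4% and 30.1%). Spread between the 2 samples of a group, as a chi-square per degree of freedom of gene counts over all cells, was 10.3 in 5xFAD_Ab3FTnAu, 7.09 in 5xFAD_PBS and 80.7 in WT_PBS.

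The first comparison, 5xFAD_PBS against WT_PBS, asks what the amyloid model changed in each cell class. In cluster 27, genes of the state that microglia take up around plaques rose in 5xFAD_PBS. Ank (15: 27466677 to 27594909), a pyrophosphate transporter, rose from 72.2 ± 39.3 to 930.4 ± 153 CPM (log2 3.81 ± 0.32, adjusted p = 7.65e-06). Apoe (7: 19696109 to 19699188), the lipid carrier, rose from 1277 ± 905 to 4371 ± 17.2 CPM (log2 1.74 ± 0.34, adjusted p = 0.00562). The purinergic receptor gene P2ry12 (3: 59216272 to 59262871), a marker of resting microglia, fell from 1655 ± 275 to 799 ± 101 CPM (log2 -1.06 ± 0.20, adjusted p = 0.00516).

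Further genes were close to absent from cluster 27 in WT_PBS. Lpl (8: 68880491 to 68907448), a lipase, reached 252 ± 20.1 CPM in 5xFAD_PBS against 1 UMI in WT_PBS, a ratio of 54.0 (95% interval 9.58 to 2142, adjusted p = 6.97e-05). Cst7 (2: 150570415 to 150578944), which encodes cystatin F, reached 213 ± 32.5 CPM, a ratio of 45.4 (8.05 to 1803, adjusted p = 0.000196). Lilrb4a (10: 51490956 to 51496611), an inhibitory receptor gene whose reads may be shared with its paralog Lilrb4b, rose by 3.75 ± 0.42 (adjusted p = 5.05e-05). With no UMI in WT_PBS, Mamdc2 (19: 23302609 to 23448442) was at least 19.7-fold higher in 5xFAD_PBS, the secreted phosphoprotein gene Spp1 (5: 104435118 to 104441050) at least 15.9-fold and the chemokine gene Ccl4 at least 14.9-fold. The Wnt antagonist gene Dkk2 was at least 8.74-fold higher, Baiap2l2 at least 8.16-fold, the chemokine gene Ccl3 at least 7.40-fold, Lgi2 at least 6.73-fold and the receptor gene Cd244a at least 6.64-fold.

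Among genes that fell in cluster 27, the macrophage genes Mrc1 (mannose receptor) and F13a1 (coagulation factor) fell by 3.18 ± 0.71 and 3.03 ± 0.55 on the log2 scale (adjusted p = 0.0137 and 0.00361). Slc2a5, a fructose transporter gene of resting microglia, fell by 1.76 ± 0.32 (adjusted p = 0.00419), Selplg by 1.26 ± 0.25 (adjusted p = 0.00718) and the lectin gene Siglech by 0.96 ± 0.19 (adjusted p = 0.00611). Nhs, Cox5a, Spcs1, Ltc4s, Ecscr and Dynll1 fell by between 1.80 (Dynll1) and 2.95 (Nhs). Trem2, the lipid receptor gene of the plaque-associated state, was at 1078 ± 72.8 against 459 ± 491 CPM and did not pass the threshold (log2 1.10 ± 0.41, adjusted p = 0.131), nor did Tmem119 (log2 -1.10 ± 0.34, adjusted p = 0.0699), Cx3cr1 (log2 -0.40 ± 0.20, adjusted p = 0.298) or the ferritin gene Fth1 (log2 0.40 ± 0.28, adjusted p = 0.480).

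In all, 125 genes rose and 83 fell in cluster 27 of 3554 tested, from 47579 to 463940 UMIs per sample, and DESeq2 gave 62. The count of 208 became 88 without 5xFAD_PBS sample 1, 135 without 5xFAD_PBS sample 2 and 417 without WT_PBS sample 2. Of 25 named genes past the threshold, 14 passed in every fit without 1 sample that tested them, and Lgi2 was not tested without 5xFAD_PBS sample 1. Cox5a and Nhs were lost in each fit without a 5xFAD_PBS or WT_PBS sample, and Mrc1, Ecscr and Spcs1 in each of these but that without WT_PBS sample 2. Dynll1, P2ry12 and Siglech were also lost without 5xFAD_PBS sample 1, Ccl3 and Siglech without 5xFAD_PBS sample 2, and Dynll1, Ltc4s and Selplg without WT_PBS sample 1. Cells with no mitochondrial UMI, which made up 20.4% ± 3.72 of the cluster in 5xFAD_PBS and 41.4% ± 24.3 in WT_PBS, gave 58 genes. Apoe did not pass in them (log2 0.96, adjusted p = 0.304). Nor did Slc2a5, Siglech and Selplg (adjusted p = 0.0714, 0.109 and 0.0637) or Ltc4s, Ecscr and Dynll1. With equal cells per sample Apoe and P2ry12 did not pass (log2 0.81 and -0.64, adjusted p = 0.2325 and 0.208). Neither did F13a1 (log2 -2.32, adjusted p = 0.208), Siglech and Selplg (adjusted p = 0.0729 for each). In DESeq2 Mrc1 (adjusted p = 0.05295), Slc2a5 (0.203), Selplg (0.0576), Lgi2, Nhs, Cox5a, Spcs1, Ltc4s, Ecscr and Dynll1 did not pass. Mrc1 was also lost with doublets kept (0.0565) and at Leiden resolution 0.5 (0.0705).

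**Figure D1:**
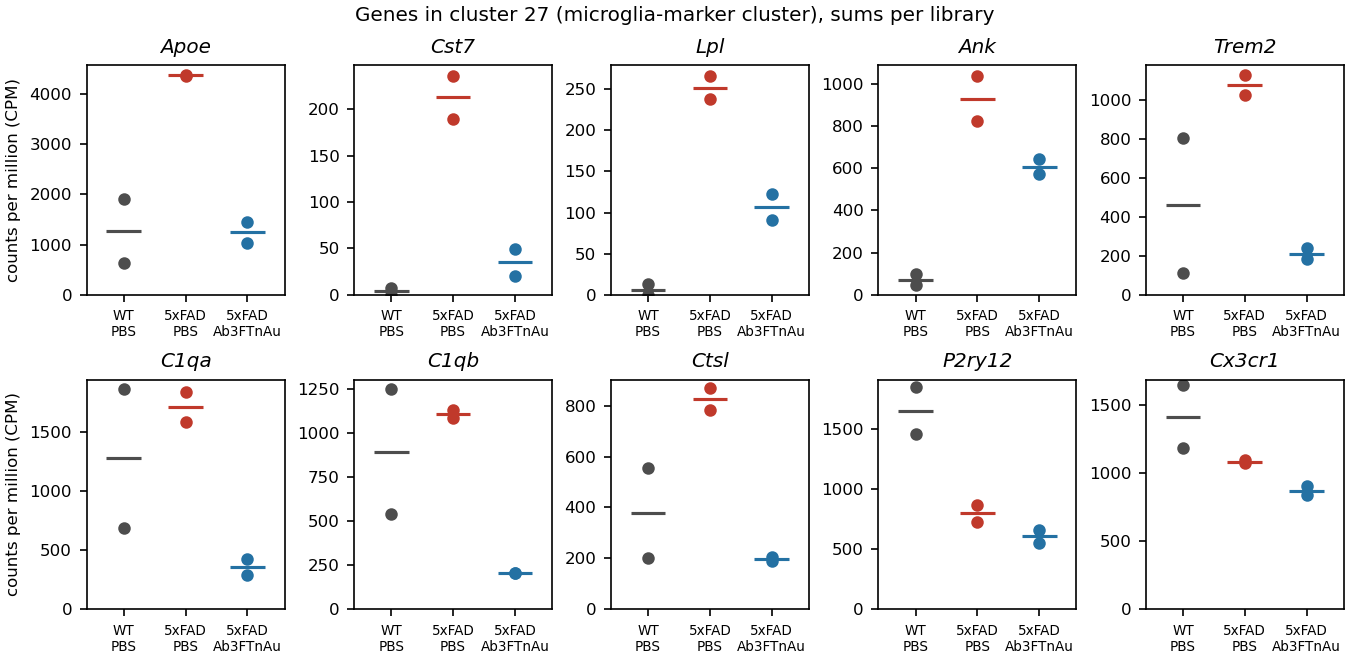
CPM of 10 genes in cluster 27 for each of the 6 samples, with a line at the mean of the 2 samples of a group. Apoe and Cst7 are highest in both 5xFAD_PBS samples, while P2ry12 is highest in both WT_PBS samples.

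The disease-associated microglia list moved as a group in cluster 27. All 24 tested members had a positive log2 fold change, with a median of 1.45, and 16 rose (20 adjusted over the list alone; camera adjusted p = 4.40e-29, adjusted p = 0.0528 with an estimated correlation, fry 0.0274). Of 20 homeostatic microglia genes, such as P2ry12 and Selplg, 6 fell and 14 did not pass (10 fell adjusted over the list alone; median -0.74, adjusted p = 2.27e-07, 0.321 with an estimated correlation). The list of inflammatory cytokines and NF-kB, with Ccl3 and Ccl4 as the 2 that rose of 4, had a median of 3.86, or 1.60 with genes at 0 set to their bound (adjusted p = 0.00989, 0.321 with an estimated correlation), and its call was lost without WT_PBS sample 2. Lipid efflux and storage genes, with Apoe and Lpl as the 2 that rose of 6, had a median of 0.65 (adjusted p = 0.00349, 0.321 with an estimated correlation), while Npc2 and Soat1 did not pass (adjusted p = 0.193 and 0.305).

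The other 11 lists tested in cluster 27 did not pass. The lysosome list had 3 genes that rose of 22 and a median of 0.04 (adjusted p = 0.163). Complement genes, 5 in number, had a median of -0.04, a mean of 0.01 and an upward test (adjusted p = 0.787). For phagocytic receptors 2 rose and 2 fell of 14, and the median of -0.18 and the mean of 0.22 differed in sign (adjusted p = 0.787). The reactive astrocyte list had a median of -0.75 and a mean of -0.15 under an upward test (adjusted p = 0.787). For oxidative phosphorylation the median of 0.06 and the mean of -0.29 also differed in sign (adjusted p = 0.470).

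Cluster 27 made up 5.18% ± 1.15 of cells in 5xFAD_PBS and 0.993% ± 0.112 in WT_PBS, a log2 ratio of 2.38 ± 0.52 that edgeR did not call (adjusted p = 0.0615). It passed without either 5xFAD_Ab3FTnAu sample (adjusted p = 0.0139 in both fits). Shares of cells depend on dissociation and capture as well as on the tissue. The oligodendrocyte-like share was 11.01% ± 0.104 against 6.87% ± 2.18 (adjusted p = 0.246), the astrocyte-like share 1.42% ± 0.550 against 3.65% ± 2.34 (adjusted p = 0.230) and the neuron-like share 64.9% ± 3.05 against 68.5% ± 0.516 (adjusted p = 0.691). No share passed in edgeR among 9 classes.

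With each cell thinned to 1000 UMIs, a Cst7 UMI was found in 53 of 278 cells of cluster 27 (19.1%, interval 14.6 to 24.2) and in 50 of 321 cells (15.6%, 11.8 to 20.01) in the 5xFAD_PBS samples. In WT_PBS it was found in 1 of 111 cells (0.901%, 0.0228 to 4.92) and in 0 of 58 cells, which allows a share of up to 5.17%. In 5xFAD_Ab3FTnAu it was found in 1 of 39 (2.56%, 0.0649 to 13.5) and 4 of 86 cells (4.65%, 1.28 to 11.5). Oligodendrocyte-like cells, which should lack Cst7, gave 10 of 514 (1.95%) and 10 of 804 (1.24%) in 5xFAD_PBS and 0 of 647 and 0 of 455 in WT_PBS, with limits of 0.464% and 0.659%. In 5xFAD_Ab3FTnAu they gave 2 of 229 (0.873%) and 3 of 450 (0.667%), so the shares of cluster 27 were not distinguishable from background in 5xFAD_Ab3FTnAu sample 1 and in both WT_PBS samples. In 5xFAD_Ab3FTnAu sample 2 the interval overlapped that of oligodendrocyte-like cells (0.138 to 1.94). Median depths before thinning were 1145 to 1295.5 UMIs in cluster 27 and 1157 to 1436.5 in oligodendrocyte-like cells.

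**Figure D2:**
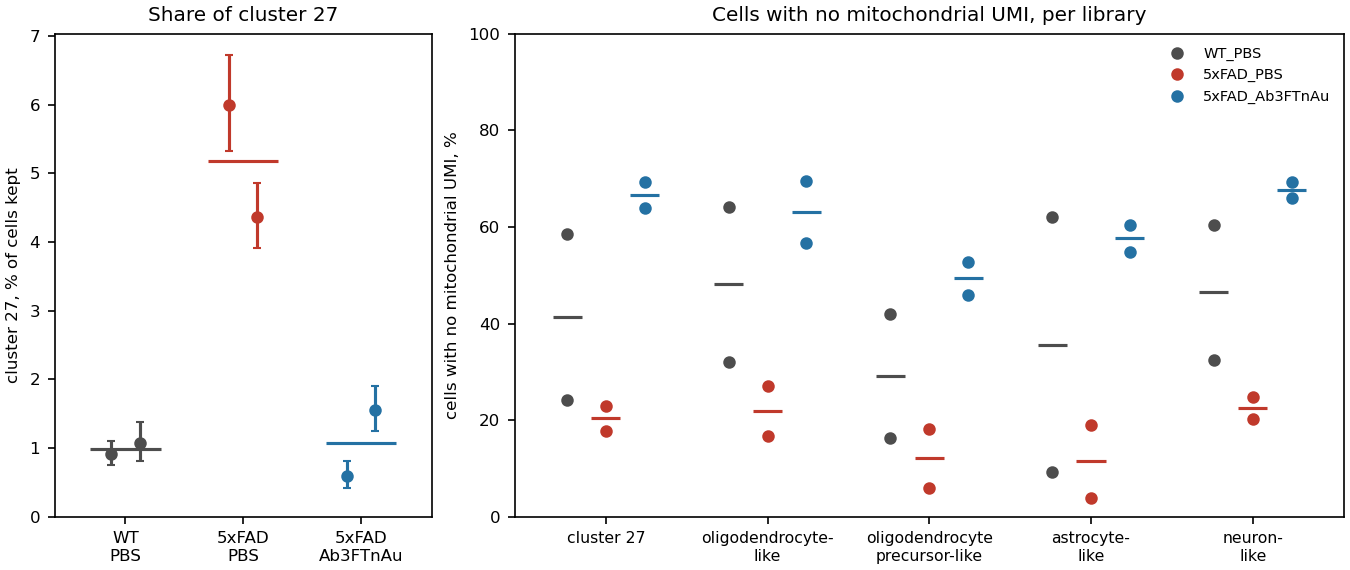
Left, the percent of kept cells that fell in cluster 27 for each sample with exact 95% intervals; right, the percent of cells with no mitochondrial UMI per cell class and sample. Cluster 27 is highest in the 2 5xFAD_PBS samples, and cells with no mitochondrial UMI are most frequent in the 2 5xFAD_Ab3FTnAu samples.

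In oligodendrocyte-like cells, the complement gene C4b rose most clearly in 5xFAD_PBS. C4b (17: 34728380 to 34743882), whose reads may be shared with its paralog C4a, went from 10.7 ± 1.23 to 345 ± 43.5 CPM (log2 5.01 ± 0.28, adjusted p = 1.23e-08). The ion channel gene Piezo2 rose from 16.6 ± 7.22 to 114 ± 4.18 CPM (log2 2.72 ± 0.28, adjusted p = 8.00e-05) and the folate enzyme gene Aldh1l2 from 9.02 ± 3.54 to 72.3 ± 8.41 CPM (log2 3.04 ± 0.35, adjusted p = 0.000295). The synaptic vesicle gene Snap25, a neuron transcript, fell from 147 ± 18.3 to 43.0 ± 2.36 CPM (log2 -1.78 ± 0.22, adjusted p = 0.000550).

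The NF-kB cofactor gene Bcl3 rose by a ratio of 21.4 (5.64 to 182, adjusted p = 0.0117), the lectin pathway protease gene Masp1 by 2.95 ± 0.48 on the log2 scale (adjusted p = 0.0120) and the interferon-induced gene Rtp4 by 2.90 ± 0.51 (adjusted p = 0.0141). Tyrobp and Trem2, a receptor pair of microglia, rose by 2.26 ± 0.37 and 2.19 ± 0.39 (adjusted p = 0.0120 and 0.0154). The class I antigen gene H2-D1, which has close paralogs, rose by 1.61 ± 0.32 (adjusted p = 0.0334). Actb (actin) fell by 1.73 ± 0.31, Ly6h fell by 1.46 ± 0.25 and the glutamate receptor gene Gria2 fell by 0.87 ± 0.17, and Pgam1 (glycolysis) fell too (adjusted p = 0.0407). Serpina3n (log2 2.24 ± 0.50, adjusted p = 0.0583), Klk6 (log2 1.46 ± 0.67, adjusted p = 0.389), Mbp (log2 0.47 ± 0.17, adjusted p = 0.254) and Il33 (log2 0.02 ± 0.16, adjusted p = 0.972) did not pass.

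In this class 23 genes rose and 18 fell of 9109, and DESeq2 gave 10. The count of 41 was 5 without either 5xFAD_Ab3FTnAu sample, 13 without 5xFAD_PBS sample 1, 7 without 5xFAD_PBS sample 2, 139 without WT_PBS sample 1 and 1107 without WT_PBS sample 2. Of 18 named genes past the threshold, C4b, Piezo2, Aldh1l2 and Snap25 passed in every fit without 1 sample. Piezo2, Aldh1l2 and Snap25 did not pass under the strict cell filter (adjusted p = 0.233, 0.338 and 0.443), nor Aldh1l2 and Snap25 with doublets kept (0.0602 and 0.197). The other 14 were lost without either 5xFAD_Ab3FTnAu sample, 10 and 13 were lost without 5xFAD_PBS samples 1 and 2, and 4, Pgam1 among them, without WT_PBS sample 1. Cells with no mitochondrial UMI were 21.9% ± 7.25 of the class in 5xFAD_PBS and 48.1% ± 22.7 in WT_PBS and gave 16 genes.

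Of 20 lists tested in oligodendrocyte-like cells, 6 were called up and 4 down. Upward were complement (1 of 4 rose, 2 adjusted over the list alone; median 0.53, adjusted p = 2.45e-12, 0.0678 with an estimated correlation), reactive astrocyte (2 of 7, 3 up and 1 down over the list alone; median 1.30, adjusted p = 9.86e-11, 0.0678) and disease-associated microglia genes (2 of 16, 8 over the list alone; median 0.42, adjusted p = 2.52e-07, 0.0678). The disease-associated oligodendrocyte list, with C4b and H2-D1 among 2 of 14 that rose, had a median of 0.55 (7 up and 1 down adjusted over the list alone; adjusted p = 1.26e-09, 0.173 with an estimated correlation). Phagocytic receptors (2 of 7, median 0.57, adjusted p = 1.15e-05, 0.148) and interferon response genes (1 of 4, median 0.84, adjusted p = 0.00125, 0.173) were also called up. Microglia markers, RNA of another class, summed to 572 ± 48.7 CPM in these cells in 5xFAD_PBS and 422 ± 99.3 in WT_PBS.

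Downward were 18 synaptic genes, such as Snap25 and Gria2, all with a negative log2 fold change (2 fell, 12 adjusted over the list alone; median -0.74, adjusted p = 6.19e-13, 0.110 with an estimated correlation). Neuron markers, RNA that oligodendrocytes should lack, summed to 1100 ± 35.6 CPM in this class in 5xFAD_PBS and 1967 ± 30.5 in WT_PBS. Oxidative phosphorylation (0 of 21 fell, 3 adjusted over the list alone; median -0.52, adjusted p = 4.46e-06, 0.205), glycolysis (1 of 9, median -0.56, adjusted p = 0.00182, 0.295) and dissociation and heat shock genes (0 of 7, median -0.61, adjusted p = 0.00190, 0.148) were lower as lists. The calls of glycolysis and of heat shock genes were lost without WT_PBS sample 1, and that of disease-associated oligodendrocyte genes without WT_PBS sample 2. The myelin list did not pass (median 0.10, adjusted p = 0.444).

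Neuron-like cells, with 20773880 to 40967396 UMIs per sample, had 0 of 19133 genes past the threshold in edgeR, 1195 at an unadjusted p under 0.05 and 26 in DESeq2. Without WT_PBS sample 1 edgeR gave 38 genes and without WT_PBS sample 2 it gave 6167, so the count depended on which WT_PBS sample was in the fit. C4b was at 2.73 ± 0.403 against 0.469 ± 0.0784 CPM (log2 2.55 ± 0.30, adjusted p = 0.585) and the lysozyme gene Lyz2 at log2 3.09 ± 0.35 (adjusted p = 0.585). Of 25 lists, 6 were called up and 3 down. Cholesterol synthesis genes, such as Nsdhl (log2 1.13 ± 0.20), were all 18 above 0 with a median of 0.43 (3 rose adjusted over the list alone; adjusted p = 1.28e-10, 0.417 with an estimated correlation), a call that passed in every fit without 1 sample. Disease-associated microglia genes, such as Trem2 and Cst7, had a median of 0.19 over 26 (5 rose adjusted over the list alone; adjusted p = 1.21e-09, 0.136 with an estimated correlation, fry 0.0323). The myelin list, with genes such as Mog and Opalin that neurons should lack, was lower (0 of 15 fell, median -0.45, adjusted p = 7.46e-05, 0.417). Microglia markers, RNA that neurons should lack, summed to 280 ± 3.29 CPM in 5xFAD_PBS and 208 ± 84.2 in WT_PBS. The calls of 6 of the 9 lists, those of disease-associated microglia and myelin genes among them, were lost without WT_PBS sample 2, 2 without WT_PBS sample 1 and 1 without each 5xFAD_PBS sample.

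Oligodendrocyte precursor-like cells had 0 of 6219 genes past the threshold in edgeR, 558 at an unadjusted p under 0.05 and 1 in DESeq2, with 18 without WT_PBS sample 1 and 716 without WT_PBS sample 2. Synaptic genes were called lower as a list (17 tested, median -0.41, 2 fell adjusted over the list alone; adjusted p = 0.00326, 0.504 with an estimated correlation), a call lost without 5xFAD_PBS sample 2. Neuron markers, which these cells should lack, summed to 1403 ± 83.3 CPM in 5xFAD_PBS and 2204 ± 15.8 in WT_PBS. None of the 4 lists called in this class passed in every fit without 1 sample. Tyrobp in these cells did not pass (log2 2.77 ± 0.70, adjusted p = 0.441).

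In astrocyte-like cells 7 genes rose and 0 fell of 3638 in edgeR, with 336 at an unadjusted p under 0.05 and 3 in DESeq2. Among them were Spag16, a cilium gene, from 29.0 ± 5.50 to 241 ± 64.7 CPM (log2 2.93 ± 0.39, adjusted p = 0.00551), and the dynein gene Dnah12 (log2 5.64 ± 0.81, adjusted p = 0.00594). Slc38a1 (glutamine transport), Plce1, Angpt1, Arhgap6 and Agbl4 rose by 2.77, 1.79, 1.55, 3.17 and 1.80, and Agbl4 was at -0.42 under the strict cell filter. The intermediate filament gene Gfap (log2 1.70 ± 0.35, adjusted p = 0.0604), C4b (log2 1.58 ± 0.35, adjusted p = 0.0779) and the water channel gene Aqp4 (log2 0.56 ± 0.26, adjusted p = 0.539) did not pass. The reactive astrocyte list was called up (5 tested, 0 rose, 2 adjusted over the list alone; median 0.37, adjusted p = 0.0218, 0.770 with an estimated correlation), and its call was lost without 5xFAD_PBS sample 2 and without WT_PBS sample 2. The count was 0 without 5xFAD_PBS sample 2, so all 7 calls were lost there, and 4 of the 7 were lost without 5xFAD_PBS sample 1 (Agbl4, Angpt1, Arhgap6 and Slc38a1) and Slc38a1 without WT_PBS sample 1. It was 20 and 179 without WT_PBS samples 1 and 2, and 28 and 29 without 5xFAD_Ab3FTnAu samples 1 and 2. Mitochondrial transcripts summed to 18560 ± 9649 CPM in this class in 5xFAD_PBS and 4339 ± 5332 in WT_PBS. Cells with no mitochondrial UMI were 11.5% ± 10.68 and 35.6% ± 37.3. No gene passed in this class with doublets kept, with equal cells or under either other cell filter. Spag16 was at an adjusted p of 0.0799 and 0.551 under the lenient and strict filters, 0.0773 with doublets kept and 0.3425 with equal cells. Dnah12 was at 0.0719 under the lenient filter and 0.0773 with doublets kept. Slc38a1, Plce1, Angpt1 and Arhgap6 did not pass in DESeq2 either.

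The second comparison, 5xFAD_Ab3FTnAu against 5xFAD_PBS, asks what the nanostructure changed in the amyloid model. In cluster 27, some complement, cathepsin and plaque-associated genes fell. C1qb (4: 136880129 to 136886187), a chain of the first complement component, fell from 1106 ± 33.7 to 205 ± 1.25 CPM (log2 -2.42 ± 0.35, adjusted p = 0.00676). C1qa (4: 136895917 to 136898803) fell from 1713 ± 180 to 353 ± 95.03 CPM (log2 -2.21 ± 0.36, adjusted p = 0.0130). Apoe fell from 4371 ± 17.2 to 1245 ± 291 CPM (log2 -1.84 ± 0.35, adjusted p = 0.0223) and the lysosomal protease gene Ctsl (13: 64359337 to 64370890) from 826 ± 61.6 to 197 ± 10.4 CPM (log2 -2.08 ± 0.35, adjusted p = 0.0131).

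Cst7 fell from 213 ± 32.5 to 35.0 ± 20.5 CPM (log2 -2.36 ± 0.47, adjusted p = 0.0295) and the signalling adaptor genes Fcer1g and Tyrobp fell by 1.95 ± 0.38 and 1.63 ± 0.31 (adjusted p = 0.0280 and 0.0223). The cathepsin genes Ctsz and Ctsb fell by 1.43 ± 0.26 and 1.40 ± 0.29 (adjusted p = 0.0158 and 0.0374). Filip1l, a filamin-binding gene, rose from 114 ± 13.8 to 331 ± 92.0 CPM (log2 1.62 ± 0.28, adjusted p = 0.0151). Trem2 was at 212 ± 39.0 against 1078 ± 72.8 CPM and did not pass (log2 -2.29 ± 0.49, adjusted p = 0.0534), nor did Cst3 (log2 -2.04 ± 0.48, adjusted p = 0.0960), C1qc (log2 -1.38 ± 0.39, adjusted p = 0.203), Lpl (log2 -1.32 ± 0.36, adjusted p = 0.198), Spp1 (log2 -2.65 ± 0.71, adjusted p = 0.198) or Fth1 (log2 -1.21 ± 0.34, adjusted p = 0.200). P2ry12, Tmem119 and Cx3cr1, markers of resting microglia, had log2 values of -0.37, -0.66 and -0.31 (adjusted p = 0.642, 0.733 and 0.697).

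In all, 2 genes rose and 17 fell, 8 of the 17 from the mitochondrial genome, and DESeq2 gave 10. Cells with no mitochondrial UMI were 66.6% ± 3.73 of the cluster in 5xFAD_Ab3FTnAu and 20.4% ± 3.72 in 5xFAD_PBS, and these cells alone gave 0 genes in edgeR with 144 at an unadjusted p under 0.05. In these fewer cells the 10 named genes past the threshold kept their direction, at log2 fold changes of -1.85 ± 0.45 for Apoe, -2.50 ± 0.44 for C1qb, -1.84 ± 0.37 for C1qa, -1.68 ± 0.38 for Ctsl, -3.20 ± 0.89 for Cst7, -1.34 for Fcer1g, -1.21 for Tyrobp, -1.42 for Ctsz, -1.25 for Ctsb and 1.19 for Filip1l. The 17 genes had a median length of 2887 bases against 60532 for all tested. With 8 of the 17 from the mitochondrial genome, that median does not describe the nuclear genes among them. The cluster held 39 and 86 cells in the 5xFAD_Ab3FTnAu samples against 278 and 321. The count of 19 became 0 without 5xFAD_Ab3FTnAu sample 2 (331 at an unadjusted p under 0.05), 49 and 29 without 5xFAD_PBS samples 1 and 2, and 109 and 121 without WT_PBS samples 1 and 2. All 10 named genes past the threshold were lost without 5xFAD_Ab3FTnAu sample 2, Cst7, Ctsz and Fcer1g without 5xFAD_Ab3FTnAu sample 1 and Filip1l without 5xFAD_PBS sample 2. With equal cells Filip1l and Ctsb did not pass (adjusted p = 0.0974 and 0.0991), under the lenient cell filter Fcer1g did not (0.113). In DESeq2 these 3, Cst7, Tyrobp and Ctsz did not pass.

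Of 15 lists in cluster 27, 10 were called lower and none higher. All 24 disease-associated microglia genes had a negative log2 fold change with a median of -1.28, and 5 fell (18 adjusted over the list alone; adjusted p = 1.47e-24, 0.203 with an estimated correlation). The 16 fixed microglia markers, which include C1qa, C1qb and Trem2, summed to 7754 ± 474 CPM in the cluster against 14170 ± 516 in 5xFAD_PBS. The 10 most specific genes of the cluster, such as Inpp5d and Ikzf1, ranged from -0.71 to 0.52 in log2 fold change with 0 past the threshold. For the lysosome, 3 of 22 fell (9 adjusted over the list alone; median -0.65, adjusted p = 2.84e-11, 0.246), for complement 2 of 5 (3 over the list alone; median -1.38, adjusted p = 1.34e-07, 0.244) and for phagocytic receptors 2 of 14 (3 over the list alone; median -0.38, adjusted p = 0.00184, 0.246). Homeostatic microglia genes were called lower as well, with 0 of 20 past the threshold (1 adjusted over the list alone; median -0.40, adjusted p = 0.00136, 0.254), a call lost in cells with no mitochondrial UMI (adjusted p = 0.176).

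The disease-associated oligodendrocyte list, which shares genes such as Cd9 and Cd63 with microglia, had a median of -1.09 over 8 (0 fell, 6 adjusted over the list alone; adjusted p = 9.86e-06, 0.203 with an estimated correlation). The unfolded protein response list had 4 members below 0 and a median of -0.91 (3 adjusted over the list alone; adjusted p = 0.00111, 0.203, fry 0.0233). Lipid efflux and storage (1 of 6 fell, median -0.67, adjusted p = 0.00136, 0.246), reactive astrocyte (1 of 5, median -1.28, adjusted p = 0.00539, 0.246) and cytokine and NF-kB genes (0 of 4, median -1.40, adjusted p = 0.0205, 0.246) lost their calls without 5xFAD_Ab3FTnAu sample 2.

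**Figure D3:**
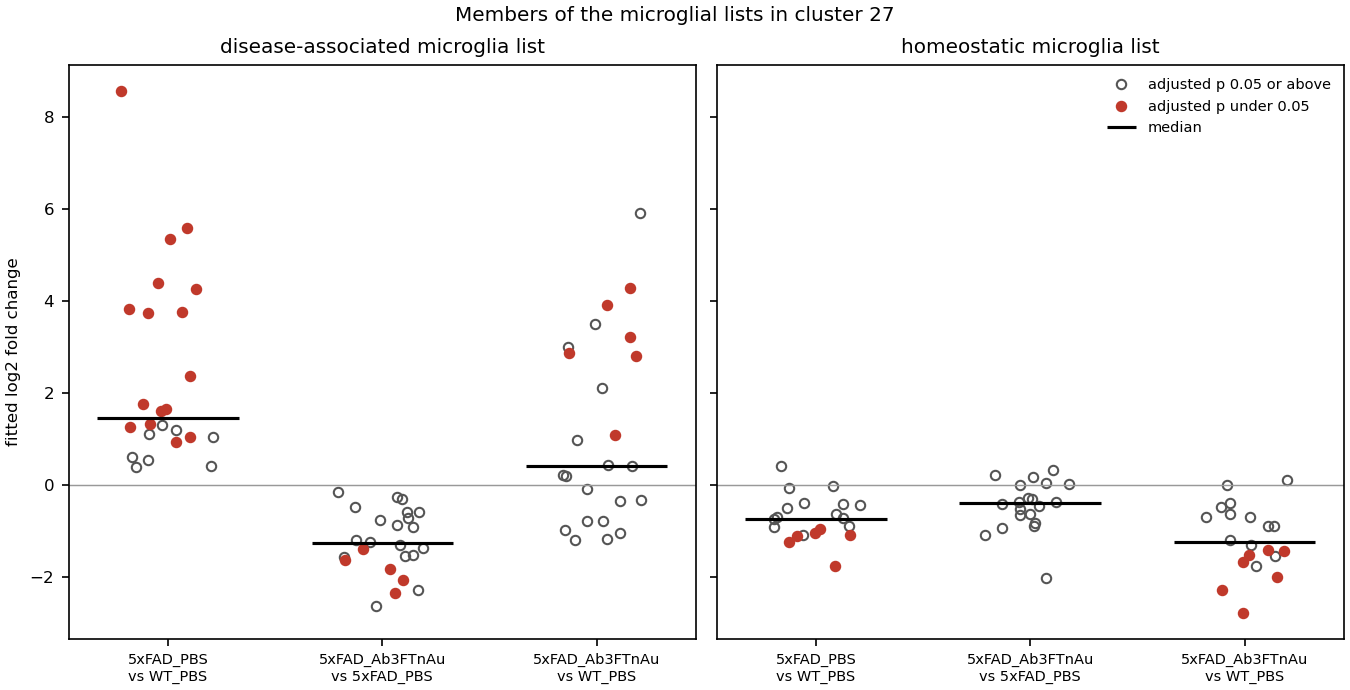
Fitted log2 fold changes in cluster 27 of the tested members of the disease-associated (24 genes) and homeostatic (20 genes) microglia lists in 3 comparisons, filled where the adjusted p is under 0.05, with a line at the median. Medians of the disease-associated list are 1.45 for 5xFAD_PBS against WT_PBS, -1.28 for 5xFAD_Ab3FTnAu against 5xFAD_PBS and 0.41 for 5xFAD_Ab3FTnAu against WT_PBS.

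The share of cluster 27 was 1.07% ± 0.676 in 5xFAD_Ab3FTnAu against 5.18% ± 1.15 in 5xFAD_PBS (log2 -2.28 ± 0.52, adjusted p = 0.0459). It missed the threshold without 5xFAD_Ab3FTnAu sample 1 (adjusted p = 0.0926), without 5xFAD_PBS sample 1 (0.172) or sample 2 (0.227) and without WT_PBS sample 1 or sample 2 (0.0875 in both fits). Cells led by mitochondrial transcripts were 0.278% ± 0.189 against 4.21% ± 1.65 (log2 -3.90 ± 0.94, adjusted p = 0.0459), a call lost without either 5xFAD_Ab3FTnAu sample (adjusted p = 0.0926 and 0.130) or either 5xFAD_PBS sample (0.172 and 0.227). The neuron-like share was 76.0% ± 3.69 against 64.9% ± 3.05 (adjusted p = 0.489) and the oligodendrocyte-like share 5.80% ± 3.27 against 11.01% ± 0.104 (adjusted p = 0.265).

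In oligodendrocyte-like cells Apoe fell from 1162 ± 216 to 347 ± 71.0 CPM in 5xFAD_Ab3FTnAu (log2 -1.77 ± 0.21, adjusted p = 0.00115). The nuclear RNA Malat1 fell by 0.64 ± 0.09 (adjusted p = 0.00321), the tubulin gene Tubb4a by 1.08 ± 0.17 (adjusted p = 0.0147) and the cystatin C gene Cst3 by 1.12 ± 0.19 (adjusted p = 0.0162). Rcan2, a calcineurin regulator, rose from 134 ± 17.1 to 268 ± 1.71 CPM (log2 1.01 ± 0.18, adjusted p = 0.0309). C4b was at 215 ± 54.0 against 345 ± 43.5 CPM (log2 -0.65 ± 0.19, adjusted p = 0.325). Tyrobp (log2 -2.28 ± 0.44, adjusted p = 0.0519), the prostaglandin synthase gene Ptgds (log2 -1.44 ± 0.28, adjusted p = 0.0519) and Mbp (log2 0.13 ± 0.17, adjusted p = 0.889) did not pass.

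The class had 1 gene that rose and 9 that fell, 5 of them mitochondrial, and 6 in DESeq2, while cells with no mitochondrial UMI were 63.2% ± 9.04 against 21.9% ± 7.25 and gave 4. EdgeR gave 0 without 5xFAD_Ab3FTnAu sample 1 or sample 2 (517 and 551 at an unadjusted p under 0.05), so all 5 named calls including Apoe were lost in both fits. It gave 6 without 5xFAD_PBS sample 2, 237 and 232 without WT_PBS samples 1 and 2, and 3 named calls were lost without 5xFAD_PBS sample 2 and 1 without sample 1. The call of Rcan2 was also lost with equal cells (adjusted p = 0.114) and those of Rcan2 and Cst3 in cells with no mitochondrial UMI (0.4735 and 0.1125). Malat1 was lost under the lenient and strict cell filters and with doublets kept (0.133, 0.102 and 0.375). Tubb4a was lost under the lenient filter, with doublets kept and at Leiden resolution 2.0 (0.0569, 0.121 and 0.0796). Cst3 and Rcan2 were lost under both cell filters. Rcan2 was also lost with doublets kept, at both Leiden resolutions and with the replicate number as a block. Of 20 lists, 11 were called lower. Disease-associated microglia genes had a median of -0.71 (1 of 16 fell, 8 adjusted over the list alone; adjusted p = 6.78e-12, 0.0872 with an estimated correlation), disease-associated oligodendrocyte genes -0.65 (0 of 14, 6 over the list alone; adjusted p = 9.82e-08, 0.207), reactive astrocyte genes -0.93 (1 of 7, 5 over the list alone; adjusted p = 2.39e-07, 0.126) and unfolded protein response genes -0.75 (0 of 10, 3 over the list alone; adjusted p = 2.25e-05, 0.126). In this class microglia markers summed to 482 ± 19.96 CPM against 572 ± 48.7 in 5xFAD_PBS, astrocyte markers to 348 ± 33.2 against 433 ± 23.8 and oligodendrocyte markers to 16060 ± 927 against 19590 ± 1275. Myelin genes such as Mag had a median of -0.36 (0 of 15, 4 over the list alone; adjusted p = 0.000424, 0.126). Complement, lysosome, phagocytic receptor, oxidative phosphorylation, lipid efflux and homeostatic astrocyte genes had adjusted p = 9.37e-05, 0.000137, 0.000396, 0.00178, 0.0187 and 0.0199 (with an estimated correlation 0.126, 0.260, 0.193, 0.324, 0.193 and 0.193). Of these, the calls of the last 2, of phagocytic receptors and of oxidative phosphorylation were lost without 5xFAD_Ab3FTnAu sample 2. That of lipid efflux was also lost without 5xFAD_Ab3FTnAu sample 1 and 5xFAD_PBS sample 2, that of oxidative phosphorylation without 5xFAD_PBS sample 2 and that of homeostatic astrocyte genes without 5xFAD_PBS sample 1.

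Neuron-like cells had 0 genes past the threshold in edgeR, 4137 at an unadjusted p under 0.05 and 1231 in DESeq2. The fit of the 4 compared samples alone gave 5961, and fits without WT_PBS sample 1 or sample 2 gave 6018 and 6023, so the count of 0 rested on the spread between the WT_PBS samples. Apoe was at 40.0 ± 1.34 against 83.8 ± 4.93 CPM (log2 -1.07 ± 0.11, adjusted p = 0.0687), the cytochrome oxidase gene Cox4i1 at log2 -0.96 ± 0.11 (adjusted p = 0.0687), the unfolded protein response gene Xbp1 at -0.95 ± 0.14 (adjusted p = 0.0725) and the growth factor gene Igf1 at 0.96 ± 0.16 (adjusted p = 0.0758). Clusters within the class differed in size between the groups. Cluster 5, with Igf1 among its 10 most specific genes, held 355 and 247 cells in 5xFAD_Ab3FTnAu and 88 and 158 in 5xFAD_PBS. With each cluster thinned to the same number of cells in every sample, Igf1 was at -0.01 (adjusted p = 0.985), against -1.01 for Apoe, -1.09 for Cox4i1 and -0.97 for Xbp1. Of 25 lists, 5 were called lower. Oxidative phosphorylation genes were all 22 below 0, and 14 fell adjusted over the list alone (median -0.62, camera adjusted p = 2.73e-09, 0.534 with an estimated correlation). Disease-associated microglia genes had a median of -0.51 (26 tested, 8 down and 1 up over the list alone, camera adjusted p = 4.69e-06, 0.256 with an estimated correlation). That list is not limited to genes that neurons lack, since it holds Igf1. Microglia markers as a sum went the other way, at 323 ± 12.98 CPM against 280 ± 3.29 in 5xFAD_PBS. Cells with no mitochondrial UMI, 67.6% ± 2.26 of this class against 22.6% ± 3.17, gave 112 genes.

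Oligodendrocyte precursor-like cells had 0 of 6219 genes past the threshold in edgeR, 436 at an unadjusted p under 0.05 and 0 in DESeq2, with 149 and 150 without WT_PBS samples 1 and 2. Apoe was at 265 ± 42.3 against 1333 ± 423 CPM and did not pass (log2 -2.32 ± 0.45, adjusted p = 0.451). Of 16 lists, 6 were called lower, among them reactive astrocyte genes (6 of 6 below 0, 1 adjusted over the list alone; median -1.02, adjusted p = 4.83e-06, 0.476 with an estimated correlation) and disease-associated microglia genes (13 tested, 3 over the list alone; median -0.81, adjusted p = 2.03e-05, 0.490). These 2 passed in every fit without 1 sample, while the other 4 were lost without 5xFAD_Ab3FTnAu sample 1 or 5xFAD_PBS sample 2, and 2 of them without 5xFAD_Ab3FTnAu sample 2. Microglia markers summed to 541 ± 4.21 CPM in these cells against 489 ± 32.5 in 5xFAD_PBS and astrocyte markers to 846 ± 4.49 against 959 ± 61.9, and cells with no mitochondrial UMI were 49.4% ± 4.81 against 12.1% ± 8.75.

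In astrocyte-like cells Apoe fell from 6940 ± 3541 to 1057 ± 3.30 CPM (log2 -2.71 ± 0.31, adjusted p = 0.000573) and passed in every fit without 1 sample, but not under the lenient cell filter (adjusted p = 0.138) or with doublets kept (0.0617). Spag16 fell by 3.50 ± 0.59 (adjusted p = 0.0193), the gap junction gene Gja1 by 1.76 ± 0.35 (adjusted p = 0.0459) and the cystine transporter gene Slc7a11 by 1.53 ± 0.31 (adjusted p = 0.0461), while the splicing factor gene Sfpq rose by 1.74 ± 0.33 (adjusted p = 0.0301). None of these calls passed under the lenient cell filter or with doublets kept either. Gfap (log2 -0.46 ± 0.37, adjusted p = 0.796), C4b (log2 -0.79 ± 0.41, adjusted p = 0.611), Aqp4 (log2 -1.15 ± 0.31, adjusted p = 0.168) and the metallothionein gene Mt1 (log2 -1.10 ± 0.46, adjusted p = 0.524) did not pass. In all 2 genes rose and 10 fell, 6 of them mitochondrial, and 5 passed in DESeq2. The count of 12 was 1 without 5xFAD_Ab3FTnAu sample 1, 2 without 5xFAD_Ab3FTnAu sample 2, 27 without 5xFAD_PBS sample 1 and 79 and 73 without WT_PBS samples 1 and 2. Spag16, Gja1, Slc7a11 and Sfpq were lost without 5xFAD_Ab3FTnAu sample 1 or 5xFAD_PBS sample 2, all but Spag16 without 5xFAD_Ab3FTnAu sample 2, and Sfpq without 5xFAD_PBS sample 1. Of 13 lists, 7 were called lower, among them disease-associated microglia (1 of 12 fell, 6 adjusted over the list alone; median -0.96, adjusted p = 5.66e-06, 0.325 with an estimated correlation) and metallothionein and oxidative stress genes (1 of 7, 2 over the list alone; median -1.10, adjusted p = 0.000211, 0.325). Mitochondrial transcripts summed to 506 ± 192 CPM in this class against 18560 ± 9649 in 5xFAD_PBS, and cells with no mitochondrial UMI were 57.6% ± 4.05 against 11.5% ± 10.68.

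The comparison of 5xFAD_Ab3FTnAu with WT_PBS in cluster 27 asks how far the treated model stood from wild type. Ank rose from 72.2 ± 39.3 to 608 ± 50.1 CPM (log2 3.21 ± 0.36, adjusted p = 0.000159), Lilrb4a by 2.87 ± 0.54 (adjusted p = 0.0103) and the adhesion gene Cadm1 by 1.08 ± 0.21 (adjusted p = 0.0127). P2ry12 fell from 1655 ± 275 to 606 ± 76.3 CPM (log2 -1.43 ± 0.23, adjusted p = 0.00355) and C1qb from 894 ± 504 to 205 ± 1.25 CPM (log2 -2.16 ± 0.36, adjusted p = 0.00565). Apoe was at 1245 ± 291 against 1277 ± 905 CPM (log2 -0.09 ± 0.35, adjusted p = 0.940).

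Lpl rose by a ratio of 21.5 (3.37 to 898, adjusted p = 0.0212) and the ligand gene Tnfsf8 by a ratio of 34.1 (5.63 to 1398, adjusted p = 0.00704). Mamdc2 was at least 13.5-fold higher, Gas2l3 at least 8.01-fold, Cd244a at least 7.59-fold, Ccl4 and Baiap2l2 at least 5.90-fold and Dkk2 at least 4.64-fold. Cst3 fell by 2.78 ± 0.49 (adjusted p = 0.00707), Selplg fell by 1.68 ± 0.32 (adjusted p = 0.0116), C1qa by 1.82 ± 0.37 (adjusted p = 0.0166), C1qc by 1.74 ± 0.40 (adjusted p = 0.0281) and Slc2a5 by 2.30 ± 0.49 (adjusted p = 0.0212). Cst7 (ratio 8.85, 1.14 to 399, adjusted p = 0.168), Trem2 (log2 -1.19 ± 0.55, adjusted p = 0.264), Tmem119 (log2 -1.76 ± 0.50, adjusted p = 0.0671) and Cx3cr1 (log2 -0.70 ± 0.22, adjusted p = 0.0911) did not pass.

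In all 78 genes rose and 41 fell, and DESeq2 gave 58. It gave no adjusted p for Gas2l3, Cd244a, Ccl4, Baiap2l2, Dkk2, Tnfsf8, Lpl and Slc2a5, so their calls rest on edgeR. The count of 119 became 13 without 5xFAD_Ab3FTnAu sample 2, 185 and 183 without 5xFAD_PBS samples 1 and 2, and 354 without WT_PBS sample 2. Of 25 named genes past the threshold 24 were lost without 5xFAD_Ab3FTnAu sample 2, all but Ank, and 16 and 6 without WT_PBS sample 1 and 5xFAD_Ab3FTnAu sample 1. Disease-associated microglia genes stayed called up (6 of 24 rose, 9 up and 1 down adjusted over the list alone; median 0.41, adjusted p = 0.000443, 0.504 with an estimated correlation), a call lost without WT_PBS sample 2 and in cells with no mitochondrial UMI (adjusted p = 0.128). In those cells Gas2l3, Ccl4, Slc2a5, Lilrb4a and Lpl did not pass either (adjusted p = 0.0679, 0.0716, 0.0679, 0.148 and 0.132). Homeostatic microglia genes were lower (7 of 20 fell, 14 over the list alone; median -1.26, adjusted p = 2.09e-12, 0.432) and complement genes too (3 of 5, median -1.74, adjusted p = 0.000443, 0.504), and both calls passed without each sample. Lysosome (0 of 22, median -0.58, adjusted p = 0.00482, 0.546), phagocytic receptor (1 of 14, median -0.41, adjusted p = 0.0305, 0.504) and unfolded protein response genes (0 of 4, median -1.09, adjusted p = 0.00939, 0.432) were called lower. The lysosome and phagocytic receptor calls were lost without 5xFAD_Ab3FTnAu sample 2 or WT_PBS sample 1, that of phagocytic receptors also without 5xFAD_Ab3FTnAu sample 1 or 5xFAD_PBS sample 2, and that of the unfolded protein response without 5xFAD_Ab3FTnAu sample 1.

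The 125 genes that rose in 5xFAD_PBS against WT_PBS had median log2 fold changes in cluster 27 of 2.18 there, 2.14 with genes at 0 set to their bound, of -0.39 for 5xFAD_Ab3FTnAu against 5xFAD_PBS and of 1.90 for 5xFAD_Ab3FTnAu against WT_PBS. Of the 125, 7 also fell in 5xFAD_Ab3FTnAu, among them Apoe and Cst7, against 0.6 for unrelated lists and 3.04 on average (6 at most) in simulated data with no changed gene, and 56 also rose in 5xFAD_Ab3FTnAu against WT_PBS, against 2.74 and 27.3 (36 at most). Of the 83 genes that fell in 5xFAD_PBS against WT_PBS, 16 also fell in 5xFAD_Ab3FTnAu against WT_PBS, within the simulated range (10.06 on average, 17 at most), and 0 rose in 5xFAD_Ab3FTnAu against 5xFAD_PBS (0.88 on average, 2 at most). Across the 208 genes called in the first comparison, 71.6% had the opposite sign in the second, against 74.6% ± 3.16 in the simulated data. Part of each overlap above unrelated lists comes from shared samples, which cannot be split with 2 per group. Over all 3554 genes the log2 fold changes of the 2 comparisons had a covariance of -0.0946, against -0.0351 ± 0.0026 simulated, and a correlation across genes of -0.197, against -0.270 ± 0.0177. The covariance was -0.041 and -0.0351 without 5xFAD_Ab3FTnAu samples 1 and 2 and -0.0512 and -0.0535 without WT_PBS samples 1 and 2 (correlations -0.0567, -0.0238, -0.0621 and -0.069). Simulated values were made for all 6 samples only. For the overlaps and the opposite signs, each simulated set gave as many genes of lowest p as were called here, with no threshold. Such genes are picked by noise alone, part of it in the shared 5xFAD_PBS samples, unlike genes called at the threshold. Their share of opposite signs is therefore no measure of what called genes would show. The simulated genes varied independently, with the same spread per gene in every group. Their ranges thus leave out correlation between genes and the wider spread within WT_PBS. Whether the covariance, the overlaps and the share of opposite signs differ from those of unchanged groups is therefore not settled.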

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

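The alternatives with cells that lack a mitochondrial UMI, equal cells per cluster and shares over named classes, and every test of the astrocyte-like class, were chosen after the data were seen. In what follows the first comparison is 5xFAD_PBS against WT_PBS, the second 5xFAD_Ab3FTnAu against 5xFAD_PBS and the last 5xFAD_Ab3FTnAu against WT_PBS. Over the alternatives that keep all 6 samples or fit the 4 compared, 3645 values of single genes and lists kept their side of the threshold. A further 389 no longer passed, 220 newly passed, 289 passed neither here nor there but moved by 1 SE or more, and 1 reversed. The reversed value was Agbl4 in astrocyte-like cells in the first comparison, at -0.42 under the strict cell filter. Of summary results, 220 kept theirs, and the others follow. The cause was not tested unless one is given.

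With the lenient cell filter, cluster 27 gave 503, 46 and 536 genes in the 3 comparisons, against 208, 19 and 119, and 13 lists in the first, against 4. Oligodendrocyte-like cells gave 17 and 2 genes in the first and second comparisons, against 41 and 10, precursor-like cells 15 in the first, against 0, and astrocyte-like cells 0 and 0, against 7 and 12. The covariance of opposed change was -0.0643 and the correlation -0.148. In the first comparison 1 class share passed, that of cluster 27, at a log2 ratio of 1.78 (adjusted p = 0.00273). The strict cell filter gave 1 gene in oligodendrocyte-like and 1 in precursor-like cells in the first comparison, with 1 list in the latter against 4. Astrocyte-like cells gave 0 and 3 genes, and 3 lists in the first, and 0 class shares passed in the second. The strict filter left no cluster 27, so its comparisons were not run.

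With doublets kept, cluster 27 gave 36 genes in the second comparison, oligodendrocyte-like cells 4 and 4, precursor-like cells 1 and 3 with 10 lists in the second against 6, and astrocyte-like cells 0 and 0 with 6 lists in the first against 1. No class share passed in the second comparison (0), and that of cluster 27 was -2.29 (adjusted p = 0.0791). Leiden resolution 2.0 gave 24 and 6 genes in oligodendrocyte-like cells and 0 class shares in the second comparison, with cluster 27 at -2.29 (adjusted p = 0.0695). Leiden resolution 0.5 gave 13 genes in precursor-like cells and 0 lists in astrocyte-like cells in the first comparison, a covariance of -0.0976, and 1 and 0 class shares, with cluster 27 at 2.43 (adjusted p = 0.0405) and -2.30 (adjusted p = 0.0509).

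With equal cells per sample, cluster 27 gave 40 genes in the first and 62 in the last comparison, oligodendrocyte-like cells 19 in the second, precursor-like cells 2 and 1, and astrocyte-like cells 0 in the first, where fewer cells entered each sum. Cells with no mitochondrial UMI gave 58, 0 and 42 genes in cluster 27, with 6 lists in the second and 2 in the last comparison against 10 and 6. There the homeostatic list no longer passed in the second (adjusted p = 0.176), nor the disease-associated list in the last (0.128). They gave 112 genes and 3 lists in neuron-like cells in the second comparison, 16 and 4 genes in oligodendrocyte-like cells with 5 lists in the first, a covariance of -0.161 and a correlation of -0.272. Precursor-like and astrocyte-like cells were too few for this setting, and it was not run there.

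DESeq2 gave 62, 10 and 58 genes in cluster 27, 26 and 1231 in neuron-like, 10 and 6 in oligodendrocyte-like, 1 in precursor-like (first) and 3 and 5 in astrocyte-like cells. With no filter on low counts, cluster 27 gave 66 and 183 genes in the second and last comparisons, neuron-like cells 414 in the second, oligodendrocyte-like cells 264 and 81, precursor-like cells 135 and 58 and astrocyte-like cells 121 and 52, with a covariance of -0.527 and 78.7% of opposite signs. Fits of only the 4 samples compared gave, in the second comparison, 48 genes in cluster 27, 5961 in neuron-like, 215 in oligodendrocyte-like, 92 in precursor-like and 61 in astrocyte-like cells, and in the first 5 in oligodendrocyte-like and 2 in astrocyte-like cells. Those fits leave out a group, so the widely spread WT_PBS samples do not enter the second comparison.

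The replicate number is shared between groups by number alone, since correlations of residuals between equal numbers ran from -0.161 to 0.048. As a block it gave 23 genes in oligodendrocyte-like cells in the first comparison, 22 and 24 in astrocyte-like cells and a covariance of -0.0912. It gave 2 and 0 class shares, with cluster 27 at 2.41 (adjusted p = 0.0494) and -2.37 (adjusted p = 0.0796). TMM over classes gave 1 class share in the first comparison, cluster 27 at 2.56 (adjusted p = 0.00379).

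With an estimated correlation, camera called 0 lists in every class and comparison. For the disease-associated list in cluster 27 the adjusted p was 0.0528, 0.203 and 0.504 in the 3 comparisons, and for the homeostatic list 0.321, 0.254 and 0.432. With fry, which does not compare a list with other genes, 2, 1 and 1 lists passed in cluster 27. The disease-associated list had 0.216 and 0.305 in the second and last, and the homeostatic list 0.178, 0.286 and 0.252 in the 3. Fry called 3 lists in neuron-like and 6 in oligodendrocyte-like cells in the first comparison, 0 in the latter in the second, and 0 and 0 in both precursor-like and astrocyte-like cells.

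Thinned to 2000 UMIs, the Cst7 shares of cluster 27 were 0 of 1 and 0 of 4 cells in 5xFAD_Ab3FTnAu, 41.7% (10 of 24) in 5xFAD_PBS sample 1 and 0 of 5 cells in WT_PBS sample 1, since few cells were that deep. Without thinning, 5xFAD_PBS sample 2 had 21.2%.

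Leaving out each sample in turn leaves 1 group with a lone sample, which is assumed to vary like the others. Counts of genes then ran, in cluster 27, from 88 to 417, from 0 to 121 and from 13 to 354 in the 3 comparisons. In neuron-like cells they ran from 0 to 6167 and from 0 to 6023, in oligodendrocyte-like cells from 5 to 1107 and from 0 to 237, in precursor-like cells from 0 to 716 and from 0 to 150, and in astrocyte-like cells from 0 to 179 and from 1 to 79. Counts of lists ran in cluster 27 from 5 to 10, 9 to 13 and 5 to 9, in neuron-like cells from 6 to 12 and 4 to 7, in oligodendrocyte-like cells from 10 to 11 and 8 to 12, in precursor-like cells from 1 to 10 and 2 to 7 and in astrocyte-like cells from 1 to 4 and 4 to 8. The adjusted p of the disease-associated list ran from 7.32e-50 to 9.36e-20, from 3.09e-35 to 2.95e-11 and from 4.82e-09 to 0.515, and that of the homeostatic list from 1.73e-16 to 0.0231, from 1.50e-06 to 0.0195 and from 1.15e-22 to 4.82e-09. Class shares past the threshold ran from 0 to 1 in both comparisons, with cluster 27 from 2.14 to 2.595 and from -3.12 to -1.74. The covariance ran from -0.1198 to -0.0351, the correlation from -0.196 to -0.0238 and the opposite signs from 60.7% to 81.5%.

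Cluster 27 held 39 cells and 47579 UMIs in its smallest sample, against 20773880 UMIs in the smallest sample of neuron-like cells.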

Other observations

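Tests of a return to the WT_PBS state, of a lower share of microglial RNA, of the minimum of UMIs per cell, of a loss of other classes and of free RNA from any source, and the use of spreads to judge the ratios and medians below, were chosen after the results were seen; by the ratios alone, less RNA from outside the nucleus and fewer cells would have been excluded for cluster 27.

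In cluster 27, disease-associated microglia genes were lower in 5xFAD_Ab3FTnAu than in 5xFAD_PBS. With the preset correlation, the list was also called lower in every other class tested. In this comparison no list was called higher in any class. The fall was thus not particular to cluster 27, but the tests of it below were run in cluster 27 alone. Gene length was argued against as the cause. The median of the list lay at percentile 0 of 10000 random lists matched on length and CPM. The lowest of these had a median of -0.86. A lower share of microglial RNA stays open. The 10 most specific genes of the cluster had a median of 0.128 (-0.227 to 0.262), but they were picked from these same cells and cannot decide. The 16 fixed microglia markers summed to 7754 ± 474 CPM in 5xFAD_Ab3FTnAu against 14170 ± 516 in 5xFAD_PBS. These markers include Trem2, which is also on the disease-associated list, and C1qa and C1qb, which were called lower. The sum thus holds part of the fall to be explained and cannot decide either. A full return to the state seen in WT_PBS would raise the homeostatic list and bring it to the WT_PBS level, but its median was -0.40 (bootstrap -0.65 to -0.16) with 15 of 20 genes below 0, and in cells with no mitochondrial UMI it was -0.133 (-0.482 to 0.185), which leaves a small rise open, and -1.15 (-1.54 to -0.538) against WT_PBS. Less RNA from outside the nucleus stays open: in cells with no mitochondrial UMI all 19 shared genes were below 0 and the list was still called (adjusted p = 4.14e-14, 0.179 with an estimated correlation), but the ratio of its median to that in all cells, 0.832, had an interval (0.544 to 1.03) that reached below the bound of 2/3. With 39 cells per sample the list was still called (adjusted p = 4.17e-12, 0.125 with an estimated correlation) and the ratio was 0.767 (0.550 to 1.19) over 15 genes, so fewer cells may also contribute, and an effect of the nanostructure was not tested.

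The share of cluster 27 was higher in 5xFAD_PBS than in both other groups. This share leaves out cluster 9, the unnamed mixture of neuron and microglia markers. Like cluster 27, it has Inpp5d, Ikzf1 and Dock8 among its most specific genes. Cluster 9 held 210 and 262 cells in 5xFAD_PBS, against 278 and 321 in cluster 27. In WT_PBS it held 440 and 162 against 111 and 58, and in 5xFAD_Ab3FTnAu 148 and 175 against 39 and 86. The size of the difference thus depends on how cluster 9 is treated. The minimum of 1000 UMIs per cell did not account for all of the higher share. The lenient cell filter lowered it to 500 UMIs, but also kept cells with 200 genes and up to 25% mitochondrial UMIs and was clustered anew. The microglia-marker class named there held 8.61% and 9.43% in 5xFAD_PBS against at most 3.28% elsewhere, 3.03 times the nearer group. With the minimum of 1000, edgeR put 5xFAD_PBS 4.84-fold above 5xFAD_Ab3FTnAu. The minimum may therefore contribute to the size of the difference, but cannot be told apart from the other changes of that filter. The matrices hold no barcode under 500 UMIs, so a still lower minimum could not be tested. A loss of other classes that spared oligodendrocyte-like cells was argued against. Cluster 27 held 54.1 and 39.9 cells per 100 oligodendrocyte-like cells in 5xFAD_PBS and 12.8 to 19.1 elsewhere. The ratio between the nearest samples was 2.09. A loss that also took oligodendrocyte-like cells would raise this ratio too, so it stays open. Different survival or capture of these cells and a larger number of them in the tissue stay open and were not tested.

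Apoe was lower in oligodendrocyte-like cells in 5xFAD_Ab3FTnAu than in 5xFAD_PBS. These cells held 0.520 and 0.411 Apoe UMIs each in 5xFAD_Ab3FTnAu, 1.54 and 1.86 in 5xFAD_PBS and 1.58 and 1.15 in WT_PBS. The 5xFAD_Ab3FTnAu samples thus lay below WT_PBS as well. In cells with no mitochondrial UMI the log2 fold change of Apoe against 5xFAD_PBS was -1.83 ± 0.23 (edgeR adjusted p = 4.70e-05), 1.04 times that in all cells. The fall was thus not limited to cells with such UMIs. A barcode without them may still hold RNA from outside the nucleus, so less of that RNA stays open. Apoe UMIs per neuron-like cell were also lower, at 0.202 and 0.251 in 5xFAD_Ab3FTnAu against 0.569 and 0.501 in 5xFAD_PBS. Free RNA from cluster 27 would carry Apoe and C1qa, C1qb and C1qc in that cluster's ratio, but the ratio in oligodendrocyte-like cells was 4.67 and 5.92 times higher in the 5xFAD_PBS samples. Free RNA from any source cannot be told apart, because oligodendrocyte-like cells held 2.71 and 3.71 times as many Apoe UMIs as neuron-like cells there, on both sides of the bound of 3 that was set. An effect of the nanostructure on these cells was not tested.

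Thy1 and App were compared over all cells as a check of the labels. Thy1 was at 193 ± 18.0 CPM in 5xFAD_PBS, 96.3 ± 3.13 in 5xFAD_Ab3FTnAu and 47.6 ± 27.6 in WT_PBS (adjusted p = 0.359 and 0.190 for the first and second comparisons). In the same order App was at 625 ± 30.4, 534 ± 6.18 and 491 ± 46.1 CPM.

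Within WT_PBS, sample 1 held 645 of the 753 astrocyte-like cells. Cluster 3, with 225 cells from all 6 samples, was led by the liver genes Fgb, Hp, Crp and Alb beside vessel markers and was not named. Cluster 9, with 1397 cells and a median of 8031 UMIs, scored 1.97 for neurons and 1.95 for microglia and was left unnamed as a mixture.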
